A study of Mus musculus with 135 samples.

How the data were processed

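Single cells of mouse thymus and intestine were sequenced by MARS-seq, which tags the 3′ end of each polyadenylated transcript with a unique molecular identifier (UMI). Per the labels' protocols, thymi of C57BL/6 mice were digested with collagenase, dispase and DNase, stromal cells were enriched on a density gradient, intestinal epithelium was released with EDTA and dispase, and stained cells were index-sorted, 1 per well. The deposited files hold counts: whole UMI numbers per gene and well for 135 plates, with 34752 wells, 33924 gene entries and 92 ERCC spike-ins, checked on every file to be whole numbers that differ in total between wells. The submitters' processing notes give bcl2fastq 2.15.0.4 and genome build mm9; the aligner, the counting program and the annotation are not given in the sources used here. No coordinates were used. A deposited table of wells gives, for part of the plates, the fluorescence intensity of each sorted cell per surface antibody, with no compensation or unit stated, the number of cells sorted, the sequencing batch and a mark for 17447 wells kept by the authors. One plate of that table is not among the samples supplied and was not used here.

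Wells with 1 sorted cell and at least 500 UMIs outside the spike-ins were kept (18985 cells, of which 1545 were not among the authors' wells); 461 wells without a sorted cell served as background. No doublet caller was run, since 1 cell was sorted per well. Groups and mice came from the sample labels: plates of 1 mouse were summed, and the mouse, not the plate or cell, was the replicate. The strain field of 1 of the 2 plates of the Sox9-GFP mouse names Pou2f3 KO in place of Sox9-GFP, and that of 1 intestinal plate, with no kept cell, Sox9-GFP; both were grouped by their description and sort. One plate could not be placed in a group and is reported only in the closing section. UMIs per mouse ranged from 224965 to 1450052 in adult TECs, from 1469594 to 2868081 at E14.5, from 627340 to 3003163 at E18.5, from 2491584 to 2646044 at day 6, from 279696 to 1027208 in stroma and from 963297 to 1161342 in intestine, with 3111518 for the mouse labelled Aire KO, 562404 for the Pou2f3 WT mouse, 1020146 and 1200071 for the Pou2f3 KO mice and 1240712 for the Sox9-GFP mouse. CD45+ mice had from 1043232 to 2910754. A gene at 20 CPM therefore rested on few UMIs in the shallowest adult mice, and genes at 0 are given with a floor of 3 counts over the group.

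Cells were clustered separately for thymic epithelium and stroma (11347 cells, 27 clusters), CD45+ cells (5718, 10) and intestine (1920, 9). Counts were scaled per cell and log-transformed, 2000 variable genes were reduced to 30 principal components, and Leiden clusters at resolution 1 were drawn from 15 nearest neighbours. A cluster took the name of the class with most fixed markers detected in at least 5% of its cells at 2 times their level elsewhere, with at least 3 such markers; 7 thymic clusters (2009 cells), 2 CD45+ clusters (251 cells) and 3 intestinal clusters (176 cells) stayed unnamed. Clusters are named by these markers, so shares of classes, not marker levels of classes against other cells of the same tissue, are reported as results.

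UMI counts summed per mouse were compared with edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood F test, two-sided, Benjamini-Hochberg at 0.05 over all genes tested) in R 4.3.3. The 4 ages shared 1 fit, as did the adult Epcam-sorted groups and the CD45+ groups; where a group had 1 mouse, its spread was taken from the other mice of the fit. SEs are the log2 fold change divided by the root of the F statistic. CPM are TMM-normalized except where values are called raw CPM, which are divided by the mouse's total alone. Lists covered tuft program, taste transduction, eicosanoid synthesis, Aire-dependent and Fezf2-dependent antigens, MHC class II, cTEC antigen processing, chemokines, keratinization, neuroendocrine, microfold, ciliated, muscle, proliferation, interferon response, stress response, type-2 cytokine, group 2 innate lymphoid, NKT, fetal TEC, intestinal and other cell type genes. The lists with at least 3 measured members (all 22, but 9 for CD45+ cells and 8 for tuft-like cells) were tested with limma 3.58.1 camera at a preset correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison. Some genes, such as *Trpm5*, *Csn2* and *Krt10*, belong to more than 1 list or also served as cluster markers. Named genes were the targeted gene, the 10 largest increases and decreases that passed, had a mean of at least 20 CPM and separated the mice of both groups, and up to 4 members of each list by p; predicted genes count but are not named. The comparison of the Pou2f3 KO mice with 9 WT adults was an alternative fixed in advance. Its genes were named by their values, after these were seen. *Spib* for the tuft-like cells, and the other genes named without passing, came from the lists.

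Shares per mouse were compared by exact permutation of mice, two-sided, adjusted over 11 classes, and median intensities of classes by exact sign-flip over 8 mice, adjusted over 20 tests. Intervals on count ratios are 95% counting intervals. The tests were checked on simulated data of each design with 100 genes changed 2-fold or 4-fold. Changed genes were drawn only from those above a minimum of expected counts in the mouse with fewest UMIs. Recovery of rarer genes was therefore not measured, and changes in class shares were not simulated. The share recovered is given for each comparison. Groups, tests, lists, markers, naming rules and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, 300 or 1000 UMIs per cell, cells thinned to 500 UMIs, other controls or cell subsets, resolutions 0.5 and 2, 15 components, a marker rule of 2 UMIs without clusters, and leaving out each mouse. Alternatives chosen after seeing the data were the authors' cells, a sequencing batch term, the younger ages without it, and leaving out or keeping clusters led by *Pth* and surfactants, defensins or *Icos*. No paired analysis was possible because every mouse belongs to 1 group. Results for 3 genes are not reported here. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used.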

Results

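The series holds 135 plates of single cells sorted from mouse thymus and, for comparison, intestine, and 18985 wells passed the cell filter. Adult CD45-negative thymic stroma came from 7 mice, and Epcam-sorted thymic epithelial cells (TECs) from 4 mice at E14.5, 3 at E18.5, 2 at postnatal day 6 and 8 adults. Each sample labelled as an E14.5 mouse held cells with *Xist* UMIs alone (4 to 23) and cells with Y-linked UMIs alone (29 to 41), so it need not be a single embryo. Smaller sorts came from 1 mouse labelled Aire KO, 1 labelled Pou2f3 WT, 2 labelled Pou2f3 KO, 1 Sox9-GFP reporter mouse gated on L1cam, and 2 Hpgds-tomato reporter mice (intestine). Cells positive for CD45 and the IL-25 receptor came from 3 WT, 3 Pou2f3 WT and 2 Pou2f3 KO mice. The median number of UMIs per cell ran from 784 in the intestinal sort to 4890 at E14.5, with 1784 in adult TECs. The mouse was the replicate throughout, and values are means ± SD over mice in CPM (counts scaled to the same total in each mouse) unless stated.

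Fibroblasts were the most frequent class in the adult CD45-negative sort, at 32.8 ± 9.55% of cells kept per mouse (n = 7). Medullary TECs (mTECs) led by *Ccl21a*, which encodes a chemokine that draws thymocytes into the medulla, made up 18.01 ± 3.04%. Endothelial cells made up 9.21 ± 7.63%, *Aire*-type mTECs, which display tissue antigens to thymocytes, 7.97 ± 2.04%, and keratinized mTECs 6.22 ± 2.89%. Tuft-like cells, recognised by *Trpm5*, *Avil*, *Lrmp* and other genes of chemosensory epithelium, made up 5.94 ± 1.47%. Thymocytes (4.55 ± 2.32%), mesothelial cells (3.22 ± 2.58%) and macrophages or dendritic cells (2.53 ± 1.51%) were less frequent, and cortical TECs (cTECs) rarer still at 0.832 ± 0.572%. Fluorescence recorded at the sort differed between endothelial cells, fibroblasts and TECs: the median CD31 signal was 11870 ± 3335 in endothelial cells (n = 4 mice) and 3.70 ± 7.21 in fibroblasts (n = 5). CD34 was 9243 ± 1976 in fibroblasts, Ly51 was 25410 ± 19240 in cTECs (n = 4), and Epcam was 6360 ± 2350 in *Aire*-type and 5921 ± 1200 in *Ccl21a* mTECs against 18 ± 4.37 in fibroblasts. These shares follow the CD45-negative gate, tissue digestion and the minimum of 500 UMIs, so they are not tissue proportions. They also depended on the clustering: at resolution 2 *Aire*-type mTECs were 14.4% and *Ccl21a* mTECs 14.2%, and at resolution 0.5 macrophages or dendritic cells were 6.67% and thymocytes 0%.

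cTECs, which support early thymocyte selection, made up 76.9 ± 0.790% of TECs at E14.5 (n = 4), 67.2 ± 7.35% at E18.5 (n = 3), 23.9 ± 0.347% at day 6 (n = 2) and 2.31 ± 1.46% in adults (n = 8). The class joined different clusters. The largest at E14.5 held 58.8 ± 1.62% of cells there and 4.91 ± 0.583% at E18.5. The largest at E18.5 held 56.7 ± 4.82% there and 2.59 ± 1.13% at E14.5. *Ccl21a* mTECs rose from 1.88 ± 0.939% at E14.5 to 40.5 ± 5.47% in adults, and *Aire*-type mTECs from 0.26 ± 0.333% to 24.8 ± 8.26%. Tuft-like cells made up 0.0458 ± 0.0916% at E14.5 (1 of 1409 cells), 0.0985 ± 0.171% at E18.5 (2 of 1096), 2.24 ± 0.169% at day 6 and 9.30 ± 3.71% in adults. Keratinized mTECs rose from 0.483 ± 0.329% at E14.5 to 6.83 ± 3.05% in adults. In two-sided exact permutation tests over 495 splits of the adult and E14.5 mice, cTECs, *Aire*-type mTECs, *Ccl21a* mTECs and tuft-like cells each reached p = 0.00202, the smallest the design allows (adjusted p = 0.00556 over 11 classes), and keratinized mTECs p = 0.00404 (adjusted p = 0.00889). Between adult and E18.5 mice, cTECs, *Ccl21a* mTECs and tuft-like cells reached the smallest p allowed, 0.00606 (adjusted p = 0.0222). Without mouse 21, 24 or 25 of the E18.5 group, 0 classes passed that comparison, the lowest adjusted p being 0.0815. No class passed between E18.5 and E14.5 (lowest adjusted p = 0.105, 3 classes at unadjusted p under 0.05). No class passed between adult and day 6 mice (smallest p allowed 0.0222, reached by cTECs and tuft-like cells; lowest adjusted p = 0.122) or between day 6 and E18.5, where the smallest p allowed was 0.1 (lowest adjusted p = 0.183). Cells of the younger mice held more UMIs (medians of 3791 to 4890 against 1784), and sequencing batches of adults and younger mice did not overlap. UMIs per cell follow both sequencing depth and RNA content, which were not told apart. Shares at each age also follow the Epcam sort, tissue digestion and the minimum of UMIs per cell, so they are not tissue proportions. Labels of the adult sort name new markers and those of the younger sorts do not. Whether the gates differed between ages was not tested.

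**Figure D1:**
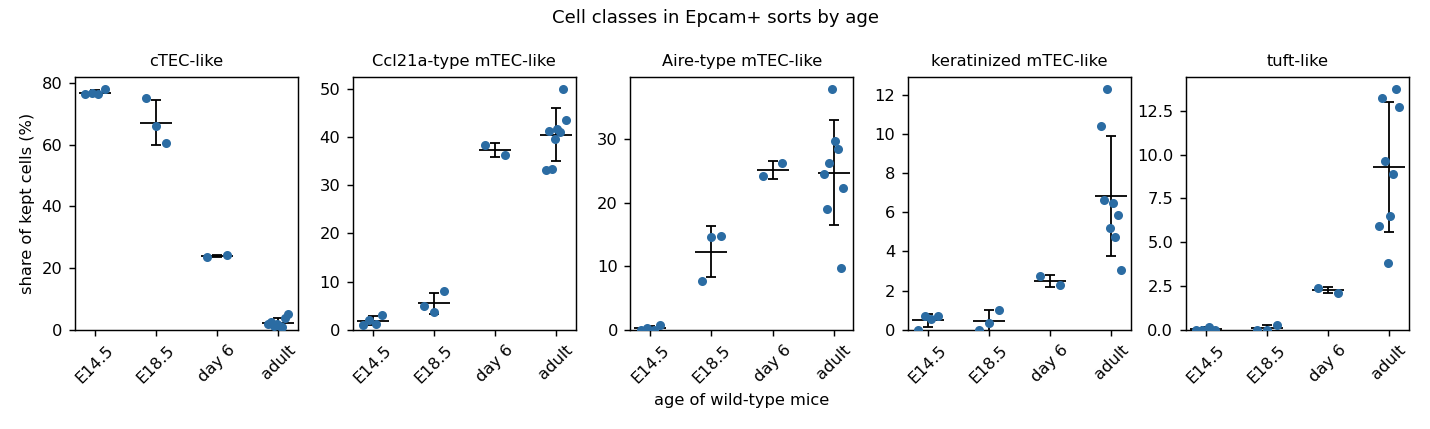
Percent of kept cells (y axis) in 5 epithelial classes against the age of WT mice (x axis). Each point is 1 mouse, the long line the mean and the error bar the SD.

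Antigen-presentation and interferon-response genes rose between E14.5 (n = 4) and E18.5 (n = 3). Here and in the later comparisons, apart from that of tuft-like cells, counts were summed over all cells of a mouse unless stated. Gene and list changes therefore include changes in class shares and need not be changes within a class. *H2-Aa*, a chain of the MHC class II molecule, rose from 1336 ± 172 to 5743 ± 1358 CPM (log2 fold change 2.10 ± 0.21 SE, edgeR adjusted p = 2.22e-07). *Isg15*, an interferon-induced ubiquitin-like protein, rose from 17.3 ± 4.63 to 235 ± 21.3 CPM (3.75 ± 0.26, adjusted p = 1.83e-09), and *Cxcl10*, an interferon-induced chemokine, from 130 ± 48.6 to 1227 ± 67.5 CPM (3.24 ± 0.29, adjusted p = 7.29e-08). Among the largest increases, the casein *Csn2*, a milk protein, reached 429 ± 149 CPM from 2.62 ± 1.88, the intestinal antimicrobial lectin *Reg3g* 909 ± 306 from 3.44 ± 2.02, and the neuropeptide gene *Calcb* 156 ± 69.1 from 1.02 ± 1.17. The airway secretoglobins *Scgb3a1* (1483 ± 1437 against 1.72 ± 1.84 CPM) and *Scgb3a2* (2128 ± 2102 against 11.3 ± 19.3 CPM) varied widely between mice, and 7385 of the 8506 *Scgb3a2* UMIs at E18.5 lay in 61 cells of the cluster that also held *Pth* and surfactant transcripts. *Ccl20*, *Muc5b*, *Gal* and *Saa3* were also among the 10 largest increases, as was the globin *Hba-a1*. Falling genes included *Tg*, the thyroid hormone precursor (52.8 ± 21.6 to 3.19 ± 4.12 CPM), *Stmn2*, a neuronal microtubule regulator (383 ± 14.4 to 95.2 ± 24.1), *Aldh1l2*, *Gnao1*, *Cpm*, *Fxyd1* and the heat-shock gene *Hspa1a*.

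Of the lists fixed in advance, all 12 interferon-response genes rose (camera adjusted p = 1.19e-29, and adjusted p = 3.32e-05 with an estimated correlation), led by *Isg15*, *Bst2*, *Usp18* and *Ifit1*. All 9 MHC class II genes rose (adjusted p = 8.32e-12, and adjusted p = 0.0358 with an estimated correlation), *H2-Oa* from 22.3 ± 3.29 to 150 ± 46.2 CPM. Of 9 chemokines 6 rose, and 7 when adjusted over the list alone, with *Cxcl10*, *Ccl21a* (47.9 ± 6.26 to 245 ± 13.01 CPM) and *Ccl22* in front. Of 6 microfold-cell genes 5 rose, among them *Tnfrsf11b* and *Spib*, a transcription factor of antigen-sampling epithelium (both lists: adjusted p = 0.0358 with an estimated correlation). Of 14 proliferation genes 7 fell and 1 rose (9 fell when adjusted over the list alone), including *Ccnb2* (192 ± 27.4 to 86.6 ± 12.7 CPM), *Cdk1* and *Birc5* (camera adjusted p = 0.000196, but adjusted p = 0.214 with an estimated correlation). Muscle genes (7 of 7, *Ttn*, *Myl1*, *Myog*), antigens known to need Aire (4 of 7, *Csn2*, *Pcp4*) and eicosanoid genes (5 of 8, *Ptgs2*, *Ptges*) rose at the preset correlation. So did ciliated-cell genes (3 of 4), intestinal genes (4 of 7, *Cdx1*), antigens needing Fezf2 (4 of 8, or 6 adjusted over the list alone, *Ttr*) and type-2 cytokines (2 of 8, *Il13*), the adjusted p running from 0.00053 to 0.0394. None of these lists passed with an estimated correlation (adjusted p = 0.138 to 0.214 with an estimated correlation). The 10 other lists did not pass, among them the tuft program (5 of 19 members higher, adjusted p = 0.117), cTEC antigen processing (2 of 10, 0.272) and fetal TEC genes (1 of 10, 0.889). Over all 14278 genes tested, 2289 were higher and 661 lower at E18.5. Without mouse 25 the counts were 1495 and 456, without mouse 21 they were 1963 and 331, and without mouse 24 they were 1851 and 340. Without mouse 22 they were 1625 and 411. With the adults left out of the fit they were 2582 and 1680, and with the sequencing batch as a further term 2508 and 1697.

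Tuft-cell genes rose between E18.5 (n = 3) and day 6 (n = 2). *Avil*, an actin-bundling protein of tuft cells, rose from 11.7 ± 2.91 to 68.6 ± 8.77 CPM (log2 fold change 2.63 ± 0.50, edgeR adjusted p = 0.00342). *Lrmp* rose from 7.03 ± 10.7 to 77.5 ± 10.01 (2.93 ± 0.58, adjusted p = 0.00459) and the taste-cell channel gene *Trpm5* from 2.77 ± 2.50 to 25.3 ± 4.51 (2.78 ± 0.61, adjusted p = 0.00954). *Ccl21a* rose from 245 ± 13.01 to 1535 ± 96.7 CPM (2.65 ± 0.29, adjusted p = 1.54e-05). Genes with large increases included insulin (*Ins2*, 63.5 ± 88.6 against 0.230 ± 0.399 CPM), somatostatin (*Sst*, 64.7 ± 51.8 against 1.35 ± 1.53), the secretory granule protein *Chgb*, the pancreatic protease *Ctrb1*, the immunoglobulin transporter *Pigr*, *Cga* and *Gfra2*. *Ins2* UMIs came from 23 cells and *Sst* UMIs from 21. *Ins2* and *Chgb* were at 126 and 187 CPM in mouse 20 but at 0.850 and 4.67 in mouse 19, so the size of their rise rested on mouse 20. *Scgb3a2* fell from 2128 ± 2102 to 4.59 ± 1.32 CPM and *Scgb3a1* from 1483 ± 1437 to 15.96 ± 15.97, along with *Agr2*, *Pir*, *Slco2b1*, *Meg3* and the immediate-early gene *Nr4a1*. *Xist* rose (73.3 ± 39.9 against 0.230 ± 0.399 CPM) while the Y-linked *Eif2s3y* and *Ddx3y* fell, so the ages differed in the sex of the mice.

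Of 19 tuft-program genes 10 rose, and 14 when adjusted over the list alone (camera adjusted p = 1.21e-11, but adjusted p = 0.0575 with an estimated correlation), *Plcb2* and *Sh2d6* among them. Taste transduction (3 of 7, or 5 adjusted over the list alone), interferon response (5 of 12, *Irf7* and *Oas1a*) and MHC class II (3 of 9, or 8 adjusted over the list alone, *H2-Oa*) moved up at the preset correlation. Eicosanoid synthesis (2 of 8, *Alox5ap* and *Ltc4s*), intestinal genes (2 of 7, *Fabp1* and *Cdhr2*), microfold genes (1 of 6, *Spib*) and chemokines (1 of 9) also moved up. So did type-2 cytokines (0 of 8, or 5 adjusted over the list alone) and NKT genes (0 of 9, or 3 adjusted over the list alone), the adjusted p of these 9 lists running from 9.57e-06 to 0.04. cTEC antigen processing (0 of 10, adjusted p = 0.000607), fetal TEC genes (1 of 10 lower, *Pax9*, adjusted p = 0.0203) and stress response (0 of 10, adjusted p = 0.04) moved down. No list passed here with an estimated correlation (adjusted p = 0.0575 to 0.404 with an estimated correlation). The 9 other lists did not pass, among them antigens needing Fezf2 (3 of 8 higher, adjusted p = 0.0561), antigens needing Aire (1 of 7, 0.12) and proliferation genes (0 of 14, 0.0831). edgeR called 523 genes higher and 209 lower at day 6, and the counts depended on single mice: 141 and 40 without mouse 20, 259 and 74 without mouse 19, 269 and 89 without mouse 24, and 274 and 100 without mouse 21. With the adults left out of the fit they were 933 and 663, and with the sequencing batch as a further term 968 and 694.

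Tuft-cell genes rose again from day 6 (n = 2) to adulthood (n = 8). *Trpm5* reached 118 ± 48.8 CPM (log2 fold change 2.21 ± 0.46, edgeR adjusted p = 0.00701), *Avil* 278 ± 112 (2.002 ± 0.42, adjusted p = 0.00722) and the leukotriene-synthesis gene *Alox5* 80.4 ± 45.7 from 13.5 ± 2.47 (2.53 ± 0.59, adjusted p = 0.0134). *Nrgn*, *Ly6g6f*, *Bmx*, *Mctp1* and the neuronal filament gene *Prph* were among the other large increases, as was the heat-shock gene *Hspa1a* (23.8 ± 4.26 to 245 ± 99.3 CPM). *Psmb11*, the thymoproteasome subunit of cTECs, fell from 681 ± 26.1 to 96.2 ± 126 CPM (−2.87 ± 0.51, adjusted p = 0.00188). Adult mouse 9 held 403 CPM of it and the other adults at most 82.5. The lung surfactant gene *Sftpc* fell from 2407 ± 1324 to 18.8 ± 20.1 CPM, with 11096 of its 11682 day 6 UMIs in 22 cells of the *Pth* and surfactant cluster. *Sftpa1*, *Hic1*, *Syngr1*, *Kcnk2*, *Cth*, *Trpm2*, *Spon2* and *Frmd6* also fell.

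Of 19 tuft-program genes 8 rose, and 16 when adjusted over the list alone (camera adjusted p = 1.24e-10, but adjusted p = 0.0785 with an estimated correlation). Of 10 cTEC antigen-processing genes 5 fell, or 8 adjusted over the list alone, *Ctsl*, *Cxcl12* and the Notch ligand *Dll4* among them (adjusted p = 3.76e-08, but adjusted p = 0.0785 with an estimated correlation). Eicosanoid synthesis rose (1 of 8, or 6 adjusted over the list alone) and fetal TEC genes fell (3 of 10, with 1 higher: *Fgfr2*, *Pax1* and *H19* fell, *Cldn4* rose), and both passed at adjusted p = 0.0493 with an estimated correlation. Taste transduction (3 of 7 higher, *Plcb2*; camera adjusted p = 0.000258), keratinization (2 of 12 higher, *Sbsn* and *Calm4*; 0.00265) and interferon response (2 of 12 lower, *Isg15* and *Ifit3*; 0.00153) passed only at the preset correlation (adjusted p = 0.0785 to 0.245 with an estimated correlation). The 15 other lists did not pass, among them MHC class II (0 of 9, adjusted p = 0.536), antigens needing Aire (0 of 7, 0.525) and proliferation genes (0 of 14, 0.21). Single members passed within such lists: *Resp18*, *Insm1* and *Hspa1b* were higher and *Chgb* lower. The fall of *Chgb* rested on mouse 20 (187 CPM, against 4.67 in mouse 19): without it the log2 fold change was 1.43 in place of −2.86, and with the authors' cells 0.741. edgeR called 233 genes higher and 559 lower in adults, 304 and 391 with RLE in place of TMM scaling, 683 and 592 with DESeq2, and 998 and 1161 with the authors' cells, so the balance of directions depended on the method. The counts rested on the day 6 mice: 13 and 120 without mouse 19, and 41 and 198 without mouse 20. Adult and day 6 mice were in different sequencing batches, so age and batch cannot be told apart.

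Across the whole span, *Lrmp* rose from 2.04 ± 1.003 CPM at E14.5 (n = 4) to 265 ± 106 in adults (n = 8; log2 fold change 6.88 ± 0.56, edgeR adjusted p = 1.51e-09). *Il13*, a type-2 cytokine gene, rose from 0.280 ± 0.559 to 121 ± 50.6 (8.45 ± 0.57, adjusted p = 1.02e-10). *H2-Aa* rose from 1336 ± 172 to 8731 ± 1794 CPM (2.71 ± 0.19, adjusted p = 1.58e-10) and *Ccl21a* from 47.9 ± 6.26 to 961 ± 324 (4.33 ± 0.25, adjusted p = 1.2e-11). *Psmb11* fell from 1328 ± 112 to 96.2 ± 126 CPM (−3.83 ± 0.45, adjusted p = 2.93e-07), and *Pax1*, a transcription factor of the early thymus, from 707 ± 55.6 to 104 ± 93.0. The adult mean of *Psmb11* was raised by mouse 9 (403 CPM, next 82.5). Several genes had no UMI at E14.5, so their folds are lower bounds against a floor of 3 counts over the group: the eosinophil granule gene *Prg2* (113 ± 68.8 CPM in adults) was at least 297-fold higher, the microfold receptor gene *Gp2* at least 322-fold. *Fam25c* was at least 390-fold higher, *Sftpd* at least 242-fold, the kallikreins *Klk1b16* and *Klk1b11* at least 305-fold and 203-fold, and the skin barrier genes *Sprr1b* and *Rptn* at least 185-fold and 182-fold. The size of the *Rptn* rise rested partly on mouse 9, at 343 CPM against at most 76.6 in the other adults. *Saa3* rose from 0.753 ± 0.692 to 676 ± 528 CPM, and the iron hormone gene *Hamp* had a count ratio of 1469 (95% counting interval 263 to 58070). The genes falling most included *Crabp2* (462 ± 46.6 to 28.5 ± 28.5 CPM), the fetal RNA-binding protein gene *Igf2bp3*, *Gpr30*, *Itgb7*, *Mfap2*, *Hic1*, *Atp7b* and *Frem2*.

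All measured members of 11 lists rose, and 10 of these lists passed camera at the preset correlation. All 12 interferon-response genes (adjusted p = 0.00111 with an estimated correlation) and all 8 eicosanoid genes (adjusted p = 0.016 with an estimated correlation) rose, and those lists also passed with an estimated correlation. The 19 tuft-program genes, 9 MHC class II genes, 6 microfold genes, 8 Fezf2-dependent and 7 Aire-dependent antigens rose without passing so (adjusted p = 0.0634 to 0.0838 with an estimated correlation). The same held for 12 keratinization, 9 NKT and 8 group 2 innate lymphoid genes (adjusted p = 0.0636 to 0.196 with an estimated correlation). Intestinal genes (6 of 7, *Cdx1* and *Vil1*), taste transduction (6 of 7, *Gng13*), type-2 cytokines (7 of 8), chemokines (7 up and 2 down of 9) and genes of other cell types (8 of 10, *Lyz2*) rose, with camera adjusted p from 0.000334 to 0.0193. None of these passed with an estimated correlation (adjusted p = 0.0634 to 0.0913 with an estimated correlation). Proliferation genes fell (12 of 14, *Top2a* 601 ± 51.0 to 204 ± 108 CPM; adjusted p = 4.35e-05, adjusted p = 0.135 with an estimated correlation). So did cTEC antigen processing (9 of 10; 0.000192, adjusted p = 0.121 with an estimated correlation) and fetal TEC genes (6 of 10, with 1 higher; 0.00507, adjusted p = 0.0634 with an estimated correlation). Neuroendocrine (3 of 4 higher, camera adjusted p = 0.0726), ciliated (4 of 4, 0.084), muscle (6 of 7, 0.102) and stress genes (3 up and 2 down of 10, 0.594) did not pass as lists. edgeR called 4610 genes higher and 3196 lower in adults, or 468 and 2269 among cTEC-like cells alone. The cTEC-like cells numbered 2 to 10 per adult mouse and lay mostly in another cluster than those of E14.5, so these counts rest on few adult cells. Age coincided with sequencing batch and with a median of 1784 against 4890 UMIs per cell. Y-linked transcripts also differed, at 20.2 to 37.4 raw CPM in the E14.5 samples and at most 3.78 in adults. Sums over all cells also follow the class shares, which differed between these ages.

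In the mouse labelled Aire KO (n = 1) *Aire* itself was detected at 1285 CPM, against 523 ± 236 in 8 WT adults (log2 fold change 1.29 ± 0.43, edgeR adjusted p = 0.22). A 3′ tag outside the deleted part checks nothing about the protein, and the allele is not given in the sources used here. Among the genes that fell, the pancreatic polypeptide gene *Ppy* (102 ± 39.8 CPM in WT) had no UMI and was at least 106-fold lower (adjusted p = 0.00507). The gut hormone gene *Gip* was at least 56.6-fold (adjusted p = 0.015), the neutrophil peroxidase gene *Mpo* at least 51.2-fold (adjusted p = 0.015) and *Dlk1* at least 68.3-fold (adjusted p = 0.0279), each against a floor of 3 counts in that mouse. *Prss29*, *Ngp*, *Cytl1* and the chemokine gene *Ccl1* were likewise at 0, and the goblet-cell peptide gene *Tff3* (0.704 against 162 ± 100 CPM) and *Crabp1* had count ratios of 267 (73.6 to 2207) and 305.5 (54.55 to 12090). *Ins2* was at 0 against 52.7 ± 36.5 CPM without passing (adjusted p = 0.0718), and *Csn2*, also listed among antigens needing Aire, was at 2012 against 506 ± 355 CPM (adjusted p = 0.372). Rising genes were led by the parathyroid hormone gene *Pth* (895 against 3.52 ± 3.44 CPM, 7.91 ± 0.40, adjusted p = 2.39e-08), with 2330 of its 2541 UMIs in 5 cells. *Il12a*, a subunit of an inflammatory cytokine (285 against 44.8 ± 21.4 CPM, adjusted p = 0.0127), the prostaglandin synthase gene *Ptgs2* (280.3 against 56.3 ± 16.1, adjusted p = 0.00397) and *Il13* (526 against 121 ± 49.98, adjusted p = 0.0238) also rose. So did *Fam19a1*, *Prokr2*, *Psd3*, *Cyp26a1*, *Nrg1*, *Dpp10*, the synaptic gene *Syn2* and the endocrine genes *Chga* and *Insm1*; *Chga* did not differ once the *Pth* and surfactant cluster was left out (−0.04, adjusted p = 0.996).

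Eicosanoid genes rose as a list (1 of 8 members, *Ptgs2*, or 3 adjusted over the list alone; camera adjusted p = 3.01e-05, and adjusted p = 0.0467 with an estimated correlation). MHC class II (0 of 9, or 8 adjusted over the list alone; 2.88e-08, but adjusted p = 0.164 with an estimated correlation) and neuroendocrine genes (2 of 4, *Chga* and *Insm1*; 0.00977, but adjusted p = 0.154 with an estimated correlation) moved up, the rise of *Chga* resting on the 5 *Pth*-rich cells. Antigens needing Aire (0 of 8, or 3 adjusted over the list alone; 0.0242, but adjusted p = 0.164 with an estimated correlation) moved down. Keratinization (0 of 12; 0.0186) and proliferation genes (0 of 14; 0.00977) also moved down at the preset correlation only (adjusted p = 0.589 with an estimated correlation for both). The other 16 lists did not pass. edgeR called 76 genes higher and 43 lower of 12669, DESeq2 115 and 186. An unnamed cluster led by *Sncg*, *Nos2* and *Il13* held 42.9% of this mouse's cells against 9.02 ± 2.97% in WT adults, *Aire*-type mTECs 19.2% and keratinized mTECs 1.51%. Most of these *Aire*-type cells (13.9% of the mouse's cells) lay in a cluster with no WT adult cells, while the *Aire*-type cluster with 18.7 ± 5.10% of WT adult cells held 0.07205% here. Counts were summed over all cells, so gene and list changes here include these differences in shares. They need not be changes within a class. *Il13* and *Il12a*, which rose, were among the leading genes of the *Sncg* cluster. With 1 mouse and its own sequencing batch, genotype, mouse and batch cannot be told apart.

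Tuft-like cells were nearly missing from the Pou2f3 KO mice, whose targeted gene encodes the transcription factor that tuft cells require. They numbered 1 of 1265 cells (0.0783 ± 0.111%, n = 2), against 8 of 401 (1.995%) in the mouse labelled Pou2f3 WT and 8.49 ± 4.24% over all 9 WT adults. A two-sided exact test gave p = 0.0182, the smallest that 55 splits allow (adjusted p = 0.2 over 11 classes). *Pou2f3* UMIs were 5 and 9 in KO mice 27 and 28 and 6 in WT mouse 26, and a 3′ tag outside the deleted part checks nothing (edgeR adjusted p = 0.961). Against the 1 labelled control, *Lrmp* was 6.50 ± 5.04 against 98.6 CPM (adjusted p = 0.409), *Trpm5* 7.62 ± 1.09 against 42.0 (adjusted p = 0.696) and *Avil* 10.97 ± 5.83 against 69.4 (adjusted p = 0.69), and no gene passed. Against all 9 WT adults (raw CPM, without TMM scaling) *Lrmp* fell (6.47 ± 4.99 against 244.5 ± 116, log2 fold change −5.18 ± 0.70, edgeR adjusted p = 0.0036). So did *Avil* (10.9 ± 5.75 against 253 ± 132, −4.49 ± 0.70, adjusted p = 0.0073), *Trpm5* (7.60 ± 1.04 against 109 ± 54.5, −3.80 ± 0.65, adjusted p = 0.0167). *Plcb2*, a phospholipase gene of taste signalling, the taste G-protein subunit *Gnb3*, the prostaglandin synthase *Ptgs1*, the signalling gene *Vav1*, *Ly6g6f* and *Ovol3* fell too. Rising genes included *Chga* (877 ± 451 against 48.1 ± 27.5, adjusted p = 0.000149), *Pth* and the matrix gene *Fmod*. In the KO mice 1216 of the 1890 *Chga* UMIs lay in 6 cells of the *Pth* and surfactant cluster, which held 0.474% of their cells against 0.153% in the 8 WT adults. *Defa24*, a Paneth-cell peptide gene, was at 9.80 in 1 KO mouse and 1207 in the other.

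Against the labelled control, edgeR called 0 of 12669 genes (762 at unadjusted p under 0.05, lowest adjusted p = 0.409) and DESeq2 3 higher and 2 lower. On simulated data of this design with 100 genes of 11860 changed 4-fold, edgeR recovered 1% and DESeq2 46%. The tuft program moved down (0 of 20 members, or 4 adjusted over the list alone, median −1.32; camera adjusted p = 1.91e-07, but adjusted p = 0.399 with an estimated correlation). So did taste transduction (0 of 7, or 2 adjusted over the list alone; 0.00308, but adjusted p = 0.399 with an estimated correlation) and stress response (0 of 10; 0.00601, but adjusted p = 0.49 with an estimated correlation). The other 19 lists did not pass. Against 9 WT adults, edgeR called 25 genes higher and 18 lower, and all 20 tuft-program members had negative log2 fold changes (median −2.97), 6 passing and 16 adjusted over the list alone. KO mouse 27 shared a sequencing batch with WT mouse 26, and KO mouse 28 did not. The KO mice and WT mouse 26 carried Y-linked transcripts (88.9 to 107 raw CPM). The 8 other WT adults nearly lacked them (at most 3.78) and came from other sequencing batches, so sex and batch differed along with genotype against the 9 WT adults.

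**Figure D2:**
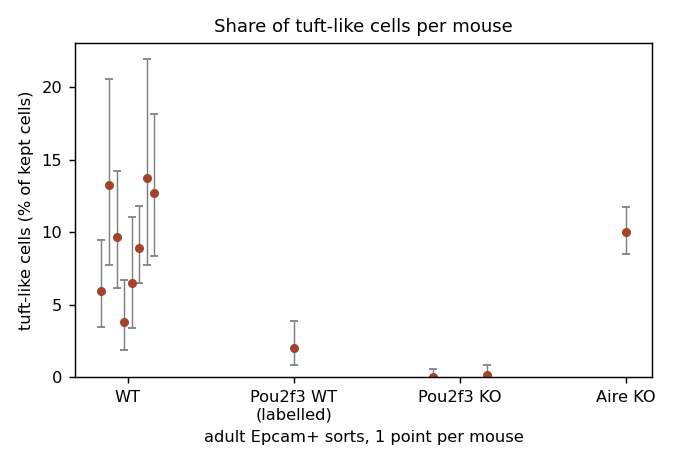
Percent of kept cells that fell into tuft-like clusters (y axis) in the adult Epcam sorts (x axis). Each point is 1 mouse, with its 95% binomial interval over cells.

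**Figure D3:**
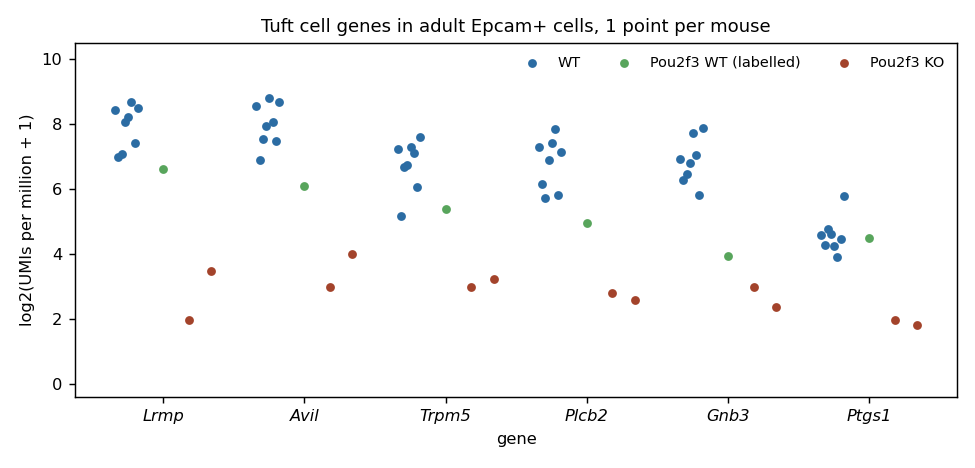
Log2 of raw CPM plus 1 (y axis) of 6 tuft-cell genes (x axis) in adult Epcam-sorted mice. Each point is 1 mouse, coloured by its labelled genotype.

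The Sox9-GFP and L1cam gate gave mostly tuft-like cells: 93.4% of the cells kept from the 1 mouse (368 of 394), against 9.30 ± 3.71% in 8 WT adults without this gate. *Avil* was at 3520 CPM against 278 ± 113 (log2 fold change 3.67 ± 0.39, edgeR adjusted p = 3.62e-05), *Trpm5* at 1535 against 119 ± 49.1 (3.71 ± 0.41, adjusted p = 5.84e-05), and *Gng13*, a taste G-protein subunit, at 2703 against 262 ± 122. The calmodulin-binding *Nrgn*, the mucosal defence gene *Dmbt1* (1588 against 4.78 ± 4.32 CPM), *Dusp5*, *Ly6g6d* and *Tmem45b* were among the genes that rose most. *Ptgs1* (442 against 24.9 ± 11.7 CPM), *Alox5ap*, the sweet and umami receptor gene *Tas1r3* and the IL-25 receptor gene *Il17rb* (219 against 17.4 ± 11.7) rose with them. *H2-Aa* fell from 8723 ± 1748 to 867 CPM (−3.33 ± 0.44, adjusted p = 0.000179), and *Foxn1*, the master regulator of TECs, from 233 ± 60.5 to 24.3. *Calca*, *Vmo1*, *Serpinb12*, *S100g* and *Igfbp6* had no UMI and were at least 82.4-, 86.7-, 39.4-, 54.4- and 30.7-fold lower against a floor of 3 counts. *Csn2* had a count ratio of 773 (139 to 30550) and the ribosomal protein gene *Rpl29* (1.73 against 914 ± 298 CPM) 513 (142 to 4237).

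Of 20 tuft-program genes 19 rose, and all 20 when adjusted over the list alone (camera adjusted p = 1.2e-32, and adjusted p = 0.0459 with an estimated correlation), and of 8 eicosanoid genes 5 rose and 1 fell (1.28e-05, and adjusted p = 0.0459 with an estimated correlation). Taste transduction rose (6 of 8, or 8 adjusted over the list alone; 8.87e-11, but adjusted p = 0.0531 with an estimated correlation), as did stress response (7 of 10, *Fos* 5584 against 578 ± 238 CPM, *Atf3*; 3.5e-09, but adjusted p = 0.0948 with an estimated correlation). MHC class II (8 of 9; 8.87e-11), chemokines (4 of 9, *Cxcl10*; 0.000779), proliferation (6 of 14, *Cdk1*; 0.000779) and type-2 cytokines (2 of 7, *Il13*; 0.00604) fell. So did antigens needing Fezf2 (3 of 8) or Aire (4 of 8), cTEC antigen processing (4 of 10), neuroendocrine (1 of 4, *Insm1*) and fetal TEC genes (1 of 9), at adjusted p from 0.0078 to 0.0279. None of the falling lists passed with an estimated correlation (adjusted p = 0.0948 to 0.412 with an estimated correlation). The 9 other lists did not pass, among them keratinization (0 of 12, adjusted p = 0.99), microfold genes (0.849, *Spib* and *Gp2* higher, *Ccl9* and *Tnfrsf11b* lower) and interferon response (0.304, *Irf7* higher and *Bst2* lower). edgeR called 1005 genes higher and 867 lower of 12376, and DESeq2 876 and 1179. In the ungated sort, tuft-like cells had the higher median L1cam fluorescence in 8 of 8 adult mice (3645 ± 1969 against 685 ± 277; two-sided exact sign-flip test, p = 0.0078, the smallest that 256 patterns allow, adjusted p = 0.012 over 20 tests). They had lower MHC-II (4876 against 23260) and Itgb4 (7186 against 15980) in every mouse and higher Epcam (33060 against 15450). *Aire*-type mTECs had the higher MHC-II (52020 against 8888), keratinized mTECs the higher Ly6d (51450 against 2520) and *Ccl21a* mTECs the higher Itgb4 (19150 against 11050), and 17 of the 20 tests passed. Transcripts of MHC class II, *Itgb4* and *L1cam* were among the markers that named the *Aire*-type, *Ccl21a* and tuft-like clusters. The direction of those tests partly follows from the naming. The gate names L1cam, so the tuft-like share of the gated mouse partly follows from it, and 1 mouse gives no spread of its own.

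**Figure D4:**
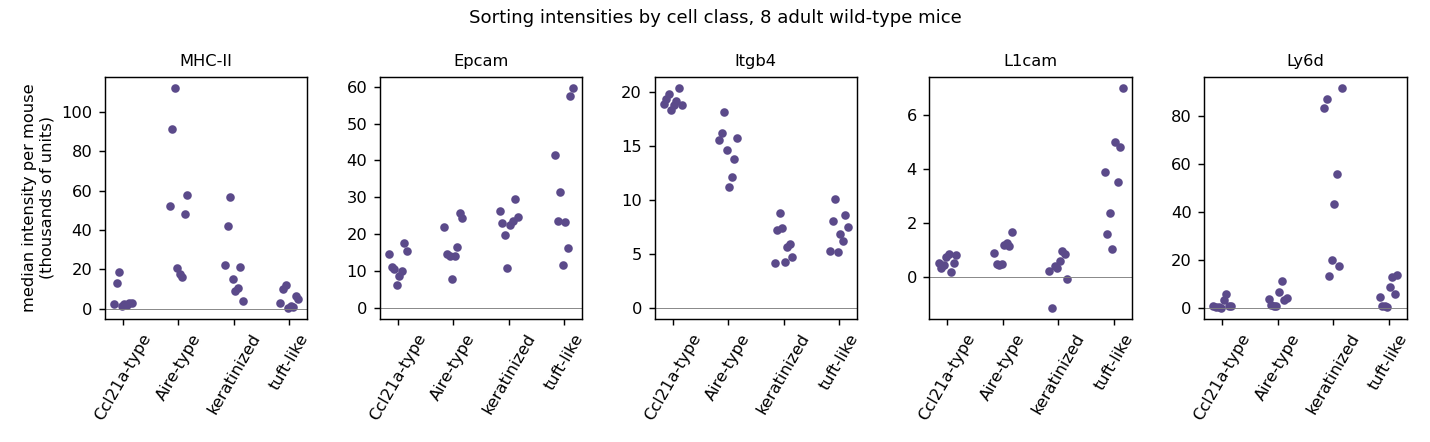
Median fluorescence at the sort (y axis, deposited units divided by 1000) of 5 surface proteins in 4 TEC classes (x axis). Each point is 1 of 8 adult WT mice.

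Intestinal tuft-like cells (n = 2 mice) and thymic ones (n = 3 WT adults with at least 20 such cells: mice 10, 13 and 15) differed in genes of their tissues. *Trpm5*, a marker by which both were named, was at 5020 ± 111 and 1708 ± 104 CPM (log2 fold change 1.55 ± 0.24, edgeR adjusted p = 0.000165). *Fabp1*, a fatty-acid carrier of enterocytes, was at 7660 ± 519 CPM in intestine without a UMI in thymus, at least 311-fold higher, as were the galectin gene *Lgals4* (at least 217-fold), *Tm4sf4* (at least 128-fold) and the gut transcription factor gene *Hnf4a* (at least 19.7-fold). *Sh2d6* (11250 ± 147 against 1206 ± 282 CPM), *Il17rb* (970 ± 4.28 against 89.0 ± 26.5), *Ptgs1*, *Ltc4s* and the microvillus gene *Vil1* (2275 ± 14.9 against 80.1 ± 69.8) were also higher in intestine. The G-protein subunit gene *Gnb3* had no UMI in intestine against 1542 ± 252 CPM in thymus (at least 616-fold lower), and *Gng13* was lower (346 ± 30.7 against 2736 ± 262, −2.99 ± 0.29, adjusted p = 4.33e-06). *Gnb3* was among the tuft markers, and whether its 0 reflects the tissue or how it was counted in this sort was not tested. The MHC class II genes *Cd74* and *H2-Eb1* had count ratios of 2469 (440.3 to 97780) and 1028 (182 to 40870). *Ubd* (at least 189-fold), *Krt17* (at least 210-fold), *Srgn* (at least 185-fold), *Ly6d* (at least 122-fold) and the adhesion gene *Cdh2* (at least 124-fold) were lower in intestine, as were *Fos* and *Fosb*. *Spib* did not differ (0.28, adjusted p = 0.449).

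Intestinal genes rose in intestine (6 of 6; camera adjusted p = 9.35e-09, but adjusted p = 0.0923 with an estimated correlation). MHC class II (6 of 6 lower; 5.61e-07, but adjusted p = 0.278 with an estimated correlation) and cTEC genes (3 of 3 lower; 0.00361, but adjusted p = 0.376 with an estimated correlation) were higher in thymus. The tuft program split (10 up and 4 down of 20, adjusted p = 0.184), as did taste transduction (2 up and 3 down of 7, 0.11). Eicosanoid (2 of 5, 0.28) and stress genes (4 down of 10, 0.11) did not pass either, and lists with under 3 measured members were not tested. edgeR called 699 genes higher and 678 lower of 2496. Leaving out a mouse also changed the genes tested: 457 and 257 of 2947 without mouse 31, 458 and 286 of 2943 without mouse 32, 1218 and 809 of 6307 without mouse 10, 1136 and 771 of 6129 without mouse 13, and 1235 and 1053 of 6295 without mouse 15. RLE scaling moved the median log2 fold change of all genes by 0.112 here. Tissue, reporter gate, digestion and sequencing batch differed together, with 784 UMIs per intestinal cell.

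CD45+ cells gated on the IL-25 receptor were thymocyte-like in most clusters, led by genes such as *Rag1*, *Cd8a*, *Dntt* and *Cpa3*. A cluster of 192 cells led by *Icos* and *Cxcr6*, genes of activated and resident lymphocytes, made up 4.72 ± 0.58% of cells in Pou2f3 KO mice (n = 2) and 3.75 ± 1.11% in Pou2f3 WT mice (n = 3). The targeted gene had 0 UMIs in every mouse of this sort, so the sort says nothing about it. *Cd3g*, a chain of the T-cell receptor complex, was at 456 ± 17.1 against 665 ± 37.6 CPM (−0.54, edgeR adjusted p = 0.982), the receptor gene *Il17rb* at 43.0 against 60.4, and the immediate-early gene *Egr1* at 43.0 against 84.8 (−0.99, adjusted p = 0.982). No share of a cluster passed a two-sided exact test (smallest p = 0.1 against 3 mice and 0.0357 against all 6 WT mice; lowest p = 0.143). edgeR called 0 of 10741 genes (501 at unadjusted p under 0.05, lowest adjusted p = 0.105) and DESeq2 0 higher and 1 lower. In camera, 0 of the 9 lists with at least 3 measured members passed (lowest adjusted p = 0.102, stress response). On simulated data of this design, edgeR recovered 65% of 100 genes of 10449 changed 4-fold and 15% of those changed 2-fold.

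On simulated data of the other designs, edgeR recovered 54% of 100 genes changed 4-fold for the mouse labelled Aire KO (11777 genes simulated), 96% for E18.5 against E14.5 (13764) and 87% for day 6 against E18.5 (13753). It recovered 95% for adult against day 6 (13579), 99% for adult against E14.5 (13222), 32% for the Sox9-GFP gate (11392) and 89% for the tuft-like cells (1621). For 100 genes changed 2-fold the recovery was 5%, 43%, 17%, 38%, 62%, 2% and 31% in that order. In every design the changed genes were among the better-counted ones, so these shares do not hold for rarer genes.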

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

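The tests on defensins, *Pth* and *Rpl29* were chosen after the results were seen; the 2 tests of other splits of the mice were not.

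In groups of 4 to 10 mice, single animals stood apart from the rest in 26 of 145 sets of values, where the rule is set to flag about 1 in 20 by chance; sets with mostly 0 values, or sharing a mouse, need not keep to that rate. Among stromal mice, mouse 5 had 5.61% macrophages or dendritic cells (next 3.12%) and 9.18% thymocytes (next 5.14%). Among adult TEC mice, mouse 9 stood apart most often: the cTEC proteasome gene *Psmb11* (403 CPM, next 82.5), the surfactant gene *Sftpc* (63.1), the skin gene *Rptn* (343), *Crabp2* (96.0), *Mfap2* (21.9), *Alox5* (184), *Bmx* (107) and *Prokr2* (63.0), with 0.826% mesothelial cells. Mouse 11 was high in *Aire* (1030 CPM, next 634) and *Dlk1* (164), mouse 12 in *Gip* (174), mouse 13 in *Cyp26a1* (33.6) and *Prph* (132), mouse 14 in *Kcnk2* (67.3) and mouse 15 in *Frem2* (23.4). At E14.5 the values apart were small: mouse 17 in mesothelial cells (0.352%), *Ccl20* (1.29 CPM), *Hamp* (0.647) and *Scgb3a2* (40.1), mouse 18 in thymocytes (0.343%), and mouse 22 in tuft-like cells (0.183%) and *Scgb3a1* (4.47). Several of these E14.5 values stand against 0 in the other 3 mice.

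Other splits of the mice were counted for the comparisons with at least 3 mice per group. For E18.5 against E14.5, 1 of 35 splits, the real one, gave as many genes (2950, highest other 928), and the split by sequencing batch gave 0. For adults against E14.5, 1 of 60 splits drawn from 495 did (7806, highest other 1890), and the 5 other splits that kept sequencing batches whole gave 0, 0, 0, 19 and 443. The real split gave the most genes in both comparisons. Every other split put both ages into at least 1 group, which widens the spread within groups and can lower the count. The counts therefore do not measure chance alone, and the batch splits, which also mix ages, say nothing about batch. An effect of batch cannot be excluded for adults, since no batch held both ages.

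Defensin genes of intestinal Paneth cells led a cluster of 119 cells, 104 from Pou2f3 KO mouse 28 and 14 from the plate that could not be assigned to a group, and 105 *Defa24* UMIs lay in the 107 wells without a sorted cell of 1 Sox9-GFP plate. Loss of Pou2f3 is argued against: *Defa24* was at 9.80 raw CPM in KO mouse 27, within the WT range (highest 24.6), and at 600.5 in the Sox9-GFP mouse. Intestinal epithelial cells in the sort are argued against too, since *Fabp1* was 88.1 times lower in the cluster than in the intestinal sort, and *H2-Aa* was found in 66.4% of its cells against 0.417% there. Transcripts spread between wells are a possible explanation: on the plate with most wells without a cell, these held *Defa24* at 16.1 times the level of wells with a cell (12.4 to 20.8). On 8 other plates of the batch, with 32 such wells, 2 *Defa24* UMIs stood against 1.82 expected. Both lay in 1 well of the other Sox9-GFP plate, and the 6 plates of KO mouse 28, with 4 such wells each, and the unassigned plate held 0, against at most 0.475 expected per plate, so the source stays open there.

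*Pth* was higher in the mouse labelled Aire KO, and 91.7% of its UMIs lay in 5 cells that also held 1231 of the 1367 *Chga* UMIs, so parathyroid cells in the sort are a possible explanation for most of the signal. Outside this cluster *Pth* still differed (log2 fold change 4.32, adjusted p = 0.00239). It was found there in 136 of 1383 cells. Its level in *Aire*-type clusters was 0.801 times that in others (0.603 to 1.07), an interval that holds 1, so loss of Aire in medullary cells stays open. Transcripts spread between wells, raised above for defensins, were not tested for *Pth* and stay open too.

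*Rpl29* was nearly undetected in the Sox9-GFP mouse. A lack of this transcript in tuft-like cells is argued against, since the tuft-like cells of WT adults held 491 raw CPM or more (up to 999) against 0.930 in this mouse. So is the sequencing batch, whose other mice held 595 and 679. A variant of the reporter strain against the reference could explain it, but with 1 UMI in these cells and no reads in the files this stays open. The strain label is unsettled, since 1 of the 2 plates of this mouse carries the strain label of the Pou2f3 KO mice. Tuft-like cells were 368 of its 394 cells, against 1 of 1265 in the Pou2f3 KO mice, which were sorted without the L1cam gate.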

How the results depend on the processing

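The authors' cells, the batch term, the younger ages without it and the omitted *Pth* cluster were chosen after seeing the data. So were the omitted defensin cluster and the *Icos* cluster. The other settings were not.

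Of 9341 values of 421 named gene results, 8919 kept their direction and side of the threshold, 414 kept the direction without passing and 8 reversed. Many of these values leave out a mouse of the fit that is in neither group compared. Such runs test the result little, so the share kept overstates stability. Of 83 gene counts under settings other than leaving out a mouse, 58 were within 1.5 times the count reported. Thinning to 500 UMIs tests fewer genes by construction; for the other moved counts the cause was not tested.

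Genes passing were, with DESeq2, 5 for Pou2f3 KO, 301 for the Aire KO mouse, 1109 for day 6, 1275 for adult against day 6 and 1 for CD45+ cells. With no low-count filter they were 2 for Pou2f3 KO, 296 for Aire KO, 831 for tuft-like cells and 14 for CD45+ cells. After thinning, they were 2 for Pou2f3 KO, 652 for E18.5, 271 for day 6, 328 for adult against day 6, 2527 for adult against E14.5, 958 for Sox9-GFP, 285 for tuft-like cells and 1 for CD45+ cells. The authors' cells gave 1 for Pou2f3 KO and 2159 for adult against day 6. Day 6 had 1662 with a batch term and 1596 without it among the younger ages. Pou2f3 KO against all adult WT mice gave 43, cTEC-like cells alone 2737 (adult against E14.5), tuft-like cells with the Sox9-GFP mouse 2546, and the *Icos* cluster 1. ILC2-like cells were not run, as no cluster took that name.

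With an estimated correlation, lists passing numbered 0 of 3 for Pou2f3 KO, 1 of 6 for Aire KO, 4 of 12 for E18.5, 0 of 13 for day 6, 2 of 7 for adult against day 6, 2 of 18 for adult against E14.5, 2 of 13 for Sox9-GFP and 0 of 3 for tuft-like cells.

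Classes differing between adult and E18.5 numbered 5 at resolution 0.5, 6 with 15 components, 5 at 1000 UMIs and 5 by marker UMIs, against 3 reported; between adult and E14.5, marker UMIs gave 8 against 5. In stroma, *Aire*-type mTECs were 14.4% at resolution 2 and 11.3% at 1000 UMIs, *Ccl21a* mTECs 14.2% at resolution 2, macrophages or dendritic cells 6.67% at resolution 0.5 and 0.719% at 1000 UMIs, and thymocytes 0% at resolution 0.5, where they joined other clusters.

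Leaving out 1 mouse gave 0 to 0 genes for Pou2f3 KO, 93 to 149 for Aire KO, 1951 to 3212 for E18.5, 181 to 844 for day 6, 133 to 901 for adult against day 6, 6671 to 8057 for adult against E14.5, 1653 to 2050.0 for Sox9-GFP, 714 to 2288 for tuft-like cells and 0 to 2 for CD45+ cells. For gene counts, the mice left out include those of the fit in neither group compared. The 3212 for E18.5 came without adult mouse 9, and the 93 for Aire KO without Pou2f3 KO mouse 27. Classes differing ranged from 0 to 4 (adult and E18.5) and 5 to 6 (adult and E14.5). Stromal shares ranged from 29.6 to 34.3% (fibroblast), 17.2 to 18.8% (*Ccl21a* mTEC), 7.73 to 10.8% (endothelial), 7.41 to 8.44% (*Aire*-type), 5.30 to 6.64% (keratinized), 5.48 to 6.23% (tuft-like), 3.78 to 4.96% (thymocyte), 2.35 to 3.58% (mesothelial), 2.02 to 2.72% (macrophage or dendritic), 0.662 to 0.971% (cTEC) and 0.584 to 0.914% (erythroid).

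Reversed log2 fold changes, cause not tested unless stated: without the *Pth* cluster, which held their UMIs, *Chga* was −0.042 (Aire KO) and 0.83 (E18.5). Leaving out 1 mouse, *Gnb3* ranged from −0.317 (without mouse 25) to 4.17 (without mouse 22; E18.5), and *Chgb* from −3.83 (without mouse 19) to 1.43 (without mouse 20; adult against day 6). With the authors' cells *Fabp9* was −0.201 (day 6) and *Chgb* 0.74 (adult against day 6), and in cTEC-like cells alone *Ctsl* was 0.88 and *Jun* −1.0 (adult against E14.5).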

Other observations

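The test on L1cam was chosen after the result was seen.

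An unnamed cluster led by *Sncg*, *Resp18*, *Nos2*, *Il13* and *Il12a* was absent from E14.5 TECs (0%), made up 0.622% at E18.5, 2.17% at day 6 and 9.02 ± 2.97% in adults. It made up 16.9% in Pou2f3 KO mice, 5.985% in the mouse labelled Pou2f3 WT and 42.9% in the mouse labelled Aire KO. A cluster led by the mitotic genes *Ube2c*, *Cdk1* and *Top2a* took the opposite course, from 16.7 ± 3.02% at E14.5 to 0.166% in adults. The 14 proliferation genes fell less over that span (12 lower, median log2 fold change −1.33). Between E18.5 and day 6, and between day 6 and adults, 0 of the 14 passed. The share of this cluster therefore does not measure the share of dividing cells. The cluster holding *Pth*, *Sftpc* and secretoglobin transcripts made up 3.08% at E14.5, 4.96% at E18.5, 1.84% at day 6 and 0.153% in adults. As for the named classes, these shares follow the sort and are not tissue proportions. A cluster of 56 cells carried genes of motile cilia (*Foxj1*, *Dynlrb2*, *Tppp3*, *Ccno*), and 1 of 109 cells the microfold genes *Ccl6*, *Ccl9*, *Ccl20* and *Gp2*.

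The plate that could not be assigned to a group held 123 cells with a median of 1449 UMIs, of which 0.813% were tuft-like, and carried *Defa24* at 228 raw CPM. E14.5 plates held both cells with *Xist* UMIs alone (51) and cells with Y-linked UMIs alone (131), so cells of both sexes were probably present at E14.5. Sample 23 had 4 cells with *Xist* alone, as did KO mouse 28, which carried 104 raw CPM of Y-linked transcripts. For sample 23 this therefore stays unclear. E18.5 mice had at most 0.666 raw CPM of *Xist*, and day 6 mice at least 42.0.

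L1cam protein was tested as a surface mark of tuft-like cells. In 8 of 8 adult mice sorted without an L1cam gate, tuft-like cells had the higher median L1cam fluorescence, in line with the gate used for the Sox9-GFP mouse; *L1cam* transcripts were among the 12 markers that named the clusters, the stain was not. Spillover from the brighter Epcam stain was not tested.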
